A study of Mus musculus with 346 samples.

How the data were processed

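Cells that carried green fluorescent protein were taken from embryos with a Prox1-EGFP transgene, sorted by flow cytometry into plates, frozen, and turned into Nextera XT libraries, per the labels' protocols. The data are from Smart-seq2, per the labels. Reads were processed with STAR 2.5.3, Cufflinks and Cuffdiff 2.2.1 on GRCm38, per the submitters' processing notes. The read counter, the annotation release, the way the size factors were found and the filters on cells and genes are not given in the sources used here.

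The authors deposited 1 table with 20474 genes and 346 cells, whose values are on the log2 scale, with empty entries where no read was found. The unit was settled from the values, since no header names it. Each cell's values turn into whole reads after undoing the log2, subtracting 1 and multiplying by 1 factor per cell: 1647510 of 1647530 deposited values lay within 0.01 of a whole number of reads, and the other 20 belonged to 5 genes. The deposited values are therefore read as log2(reads / size factor + 1). They run from 0.448 to 17.3, 76.7% of entries are empty, and no entry is 0. Empty entries were set to 0. There were 23 gene names that a spreadsheet had turned into dates, which were left as they are, 11 Ensembl identifiers, and 20420 names that matched the annotation. No 2 cells were identical, and the highest correlation between 2 cells was 0.734. Coordinates are from GENCODE M21 on GRCm38.

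From the deposited values the mean and SD over cells of log2(normalized reads + 1) were computed for each gene and group, with the difference of means for 8 contrasts in 4 comparisons. Since the labels name no animal, each group counts as 1 sample, and no test, p-value or count of changed genes was computed. Shares of cells use 5 normalized reads as the limit of detection and carry exact Clopper-Pearson 95% intervals. A share of 0 of a whole group or plate is given with 3 divided by its number of cells as the limit, while tests of explanations use the exact upper bound. PCR reads are not independent molecules, so intervals and limits cover counting error only.

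The following choices were made before the data were examined: the groups, the contrasts, the 30 gene lists (7 of them for other cell types), the rules for clusters and named genes, and most of the alternatives. Named genes are the 10 with the largest higher and the 10 with the largest lower difference in each comparison, ranked by the smallest difference over its contrasts, all of the same sign. They had to be detected in at least 25% of the cells of 1 group, and mitochondrial, ribosomal, predicted, Xist and Y-linked genes were left out. For lists, up to 4 members with the largest differences may be named, and Prox1 is named everywhere. Genes named for a cluster are its listed markers, its 10 leading genes, or genes already named in a comparison. A list's median runs over members with a mean of at least 1 in 1 of the groups, and its place among 10000 random lists matched on 20 bins of expression (seed 1) was kept as a description. Members counted as higher or lower differ by at least 1.

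Clusters came from Leiden clustering (resolution 1, seed 0) of a graph of 15 nearest neighbours on 20 principal components of the 2000 most variable genes. A cell counted as one of another type with at least 3 markers of 1 such list, as epithelial with at least 2 epithelial genes, and as holding both programmes with at least 2 genes of each core list. Reads were recovered from the deposited values and thinned to 500000 per cell to compare genes at equal depth.

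The steps were tested on simulated cells drawn from the dorsal bud's means and spreads for all 20474 genes, with 200 genes changed in the cells that stood in for the ventral bud. Direction was right for 88.2% of 68 genes changed 2-fold, and for 100% of 63 genes at 4-fold and of 69 genes at 8-fold. Median differences there were 0.67, 1.63 and 2.44, so differences of mean log2 fall short of the log2 fold changes behind them. Of 40 unchanged lists 1 lay outside the central 95% of random lists, and clustering of simulated groups returned 5 clusters that matched them, with an adjusted Rand index of 1. Each simulated group followed 1 mean profile, so this index says nothing of groups with mixed cell types. Simulated genes were drawn independently of each other, so the result for unchanged lists says nothing of lists whose members vary together.

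Alternatives were pseudocounts of 0.1 and 10, ratios of linear means, median-of-ratios scaling over 3342 genes found in at least 50% of cells, cells with at least 2000 genes, cells without markers of other types, cells with Prox1, no filter on low members, each dorsal plate alone, other limits of detection, other gene minimums, and other cluster settings. Those added after seeing the data were cells with epithelial genes alone, scaling by each cell's total reads, cluster 1 alone, leaving out cluster 10, and thinned cells. Tools were python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9.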

Results

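Single mouse cells that carried green fluorescent protein driven by Prox1, a homeobox transcription factor of the early liver and pancreas, were sorted and sequenced with Smart-seq2, which reads full-length transcripts one cell at a time. The table holds 346 cells in 5 groups. They comprise 82 cells of the foregut at embryonic day (E) 8.5, 86 of the dorsal and 27 of the ventral pancreatic bud at E10.5, 78 of the liver at E10.5, and 73 of the pancreas at E14.5. The series description counts 452 processed cells, and those that failed quality control are not analysed here. Median reads per cell were 1029064 in the foregut (510222 to 1298431), 871446 in the dorsal bud (545035 to 1268994) and 851654 in the ventral bud (529196 to 1942199). They were 2510705 in the liver (633115 to 3431728) and 811359 at E14.5 (510724 to 1080041). The median share of mitochondrial reads was 1.33% in the foregut, 1.06% in the dorsal and 1.03% in the ventral bud, 3.09% in the liver and 1.93% at E14.5. Median genes per cell were 6430, 5568, 4202, 3133 and 3162 in the same order of groups. Median genes with any read were 6548, 5637, 4202, 3582 and 3162, and after thinning each cell to 500000 reads they were 6303, 5469, 4105, 3094 and 3040. The labels name no animal, so each group counts as 1 sample without replicates: no test was run, and each SD below describes the spread between cells. Each group came from 1 plate except the dorsal bud, which came from plates 2A (48 cells) and 2B (38 cells), so plate and group cannot be told apart elsewhere. Levels are means over cells of log2(normalized reads + 1), and a gene counts as detected in a cell at 5 or more normalized reads. Intervals are exact Clopper-Pearson 95% intervals that cover counting error only.

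Prox1, the gene behind the reporter (chromosome 1, 190118035 to 190170714, GRCm38), was detected in most cells of each E10.5 organ and of the foregut, and in a minority of the E14.5 cells. Its mean level was 5.13 ± 2.39 (SD over cells, n = 82) in the foregut, where 71 cells (86.6%, interval 77.3 to 93.1%) carried it. The dorsal bud had a mean of 8.92 ± 2.73 (n = 86) with 83 cells positive (96.5%, 90.1 to 99.3%), and the ventral bud 9.76 ± 1.03 (n = 27) with 27 cells positive (lower bound 87.2%). In the liver the mean was 8.64 ± 4.20 (n = 78), with Prox1 in 66 cells (84.6%, 74.7 to 91.8%). At E14.5 it was 3.02 ± 4.49 (n = 73), with Prox1 in 24 cells (32.9%, 22.3 to 44.9%). The dorsal plates gave 9.47 ± 2.97 (2A, n = 48) and 8.23 ± 2.26 (2B, n = 38). The table has no row for the reporter transcript itself. The groups also differed in cell types: 73 of 86 dorsal and 27 of 27 ventral cells had at least 2 epithelial genes detected. This held for 22 of 82 foregut, 36 of 78 liver and 13 of 73 E14.5 cells. The share with Prox1 did not follow these counts in the foregut (86.6%) and the liver (84.6%). Cells with at least 3 markers of a non-epithelial cell type numbered 17 in the foregut, 18 in the dorsal bud, 0 in the ventral bud, 26 in the liver and 62 at E14.5. This flag rests on the listed markers alone and need not find every cell of another type.

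**Figure D1:**
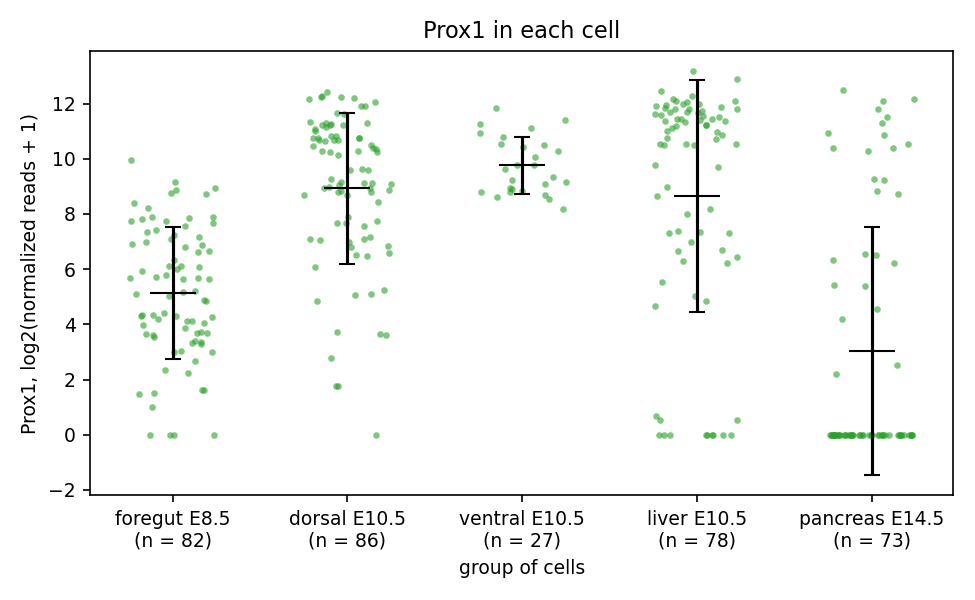
Prox1 level of each cell, as log2(normalized reads + 1), by group, with 1 point per cell and a bar and whiskers for the mean and SD over cells. Most of the 73 cells at E14.5 sit at 0, while the 27 ventral bud cells average 9.76.

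Clustering of the 346 cells gave 10 clusters, of which 4 were named from marker lists. Cluster 3 (48 cells, 46 of them from the liver and 2 from the ventral bud) was hepatoblast-like: 15 of 17 hepatoblast markers were detected, Afp, a fetal serum protein, averaged 14.53 ± 1.16, and Prox1 was present in 48 of 48 cells at 11.52 ± 0.63. Cluster 7 (20 dorsal bud cells, 23.3% of that group, interval 14.8 to 33.6%) was endocrine-like, with 14 of 15 markers. Within it the glucagon gene Gcg was detected in 14 cells, the peptide YY gene Pyy in 20 and Pcsk2, a prohormone convertase, in 19. Cluster 9 (15 cells, 12 of them from E14.5) was endocrine progenitor-like, with 10 of 10 markers. Neurog3, the transcription factor that starts endocrine differentiation, was found in 12 of its 15 cells, and Prox1 in 15 of 15 at 11.33 ± 0.74. Cluster 2 (58 cells, 79.5% of the E14.5 group, interval 68.4 to 88.0%) was mesenchyme-like, with 7 of 10 markers. The type I collagen gene Col1a1 averaged 11.64 ± 1.11 there, Prox1 was detected in 10 of 58 cells, and 0 cells had 2 or more epithelial genes. Cluster 1 (60 cells: 8 foregut, 27 dorsal, 24 ventral and 1 of E14.5) carried markers of several types, taken over the cluster as a whole, and was left unnamed. Of its cells 36 had at least 2 hepatic core genes, 34 at least 2 pancreatic core genes and 14 both, where independence would give 20.4. Pdx1, the regulator of pancreas development, was detected in 32 of its cells, Nepn, a foregut gene, in 35, and Afp in 29.

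The other clusters were also left unnamed and are described by their genes. Cluster 4 (42 foregut cells) carried Rfx4, a transcription factor known from the neural tube, in 40 cells and the neural adhesion gene Nrcam in 41, with Prox1 in 38. Cluster 8 (17 foregut cells) carried the retinoic acid binding protein genes Crabp1 and Crabp2 in 17 of 17 cells, with Prox1 in 14. At least 3 markers of a non-epithelial type were found in 3 cells of cluster 4 and 0 of cluster 8, so that flag left most of these cells in. It took out 3 cells of cluster 7 and 2 of cluster 9, the endocrine-like and endocrine progenitor-like ones. Cluster 5 (37 cells, 32 of them from the liver) had Prox1 in 23 cells, and of its liver cells 20 had at least 3 mesenchyme markers and 12 at least 3 cardiac markers. Over cluster 6 as a whole 7 of 7 cardiac markers were detected. It joined 12 foregut cells, 11 of which had at least 3 cardiac markers, to 23 dorsal bud cells. Of the latter 0 had them and 13 had mesenchyme markers. Of those 23 dorsal cells, 6 were on plate 2A and 17 on plate 2B. Cluster 10 (14 cells) came from plate 2A alone, with the metallothionein gene Mt1 in 92.9% and Pdx1 in 7 of its cells. It had 8 of 12 pancreatic progenitor markers, 4 of 10 duct markers and 0 of 15 endocrine markers.

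**Figure D2:**
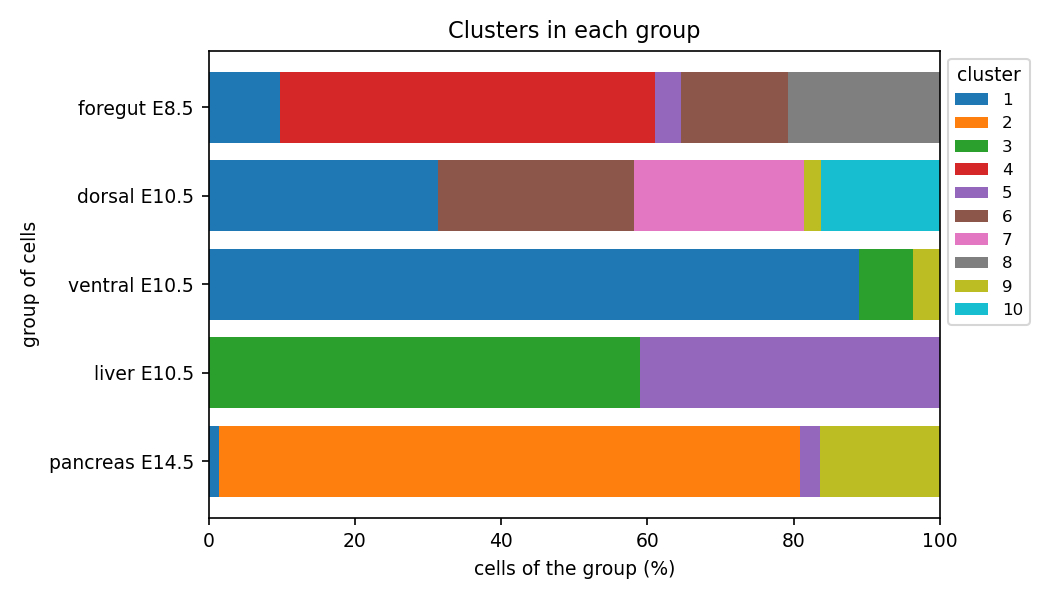
Share of each group's cells, in percent, that fell in each of the 10 clusters, with 1 bar per group and 1 colour per cluster. Cluster 2 takes 79.5% of the E14.5 cells and cluster 1 takes 88.9% of the ventral bud cells.

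Liver cells and pancreatic bud cells at E10.5 were compared to see which genes set hepatic progenitors apart from pancreatic ones at 1 stage. Liver cells carried much higher levels of genes for secreted plasma proteins, and lower levels of epithelial and pancreatic genes. Apoa1, the main protein of high density lipoprotein (chromosome 9, 46228580 to 46230466), averaged 6.78 ± 5.46 in the liver, where 48 of 78 cells had it, against 0.33 ± 1.02 in the dorsal and 0.74 ± 1.94 in the ventral bud. The albumin gene Alb (chromosome 5, 90460897 to 90476602) averaged 5.60 ± 5.27 in the liver (43 of 78 cells), 0 in the dorsal bud and 0.35 ± 1.81 in the ventral bud. Epcam, an epithelial adhesion gene (chromosome 17, 87635979 to 87651129), averaged 0.65 ± 2.18 in the liver against 6.93 ± 3.91 and 8.77 ± 2.73 in the dorsal and ventral buds. The other genes with the largest higher levels in liver included Serpina6, which encodes corticosteroid-binding globulin, the clotting regulators Serpinc1 and Serpind1, the fibrinogen gene Fga and the transferrin gene Trf. Outside the plasma proteins they included the lipase gene Lpl, the purine synthesis gene Pfas and the antiviral gene Zc3hav1. Genes with lower levels included Igfbp2, which binds insulin-like growth factors (1.15 ± 2.76 against 8.22 ± 3.12 and 8.25 ± 2.99), the tight junction gene Cldn6, the basement membrane collagen Col4a1, the progenitor factor Sox9, Pxdn, Spint1, Ddah2, Ptprk and Grn.

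By gene list, hepatic secreted proteins had a median difference of 5.50 between liver and dorsal bud, with 14 of 16 measured members higher by at least 1 and 0 lower. Between liver and ventral bud it was 2.08, with 12 higher and 2 lower. The largest members against the dorsal bud were Afp (7.98), Apoa2, an apolipoprotein gene (7.94), and the fibrinogen gene Fgb (7.18). Liver bud transcription factors differed by 1.01 from the dorsal bud and by -0.03 from the ventral bud. Among them Hnf4a, a hepatocyte regulator, differed by 2.02 and 1.60, while Hhex, needed for liver bud growth, differed by 2.94 and -2.10. Pancreatic progenitor genes were lower in liver by a median of -2.48 against the dorsal bud (0 higher and 8 lower of 12) and -1.25 against the ventral bud (0 higher and 8 lower of 12). Pdx1 was 0 in the liver against 2.69 ± 4.10 in the ventral bud. Epithelial genes differed by -3.62 and -3.94, ductal genes by -1.15 and -1.50, and biliary genes by -0.96 and -2.44. Among random lists matched on expression the biliary medians lay at percentiles 61.3 and 0, so the former was not low for genes of its level. Endocrine hormone and granule genes differed by -1.76 from the dorsal bud, and by -0.22 from the ventral bud. Glycolysis genes differed by -1.52 and -0.59. Mesenchyme markers differed by 0.54 and 1.51, and cardiac markers by 0.91 and 1.24. At least 3 mesenchyme markers were found in 20 liver cells, and at least 3 cardiac markers in 12.

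The median difference of all genes was -0.51 between liver and dorsal bud, and -0.71 after median-of-ratios scaling. Relative to the former the hepatic secreted median was 6.02 and the pancreatic progenitor median -1.97. Without cells of other types the hepatic secreted medians were 8.17 and 5.86, and in cells with at least 2 epithelial genes, which in the liver were 35 cells of cluster 3 and 1 of cluster 5, 8.84 and 6.83. In the latter cells the glycolysis medians were -0.54 and 0.19, and the dorsal plates differ from each other by -1.28 for this list. The medians of liver bud transcription factors in these cells were 1.56 and 0.51, so the latter turned direction.

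The ventral and dorsal buds form the same organ from opposite sides of the gut, the ventral one beside the liver, and they were compared to see which genes differ between them. Ventral cells carried higher levels of several liver genes, and lower levels of the endocrine regulator Isl1. The ventral cells were mixed: 21 of 27 had at least 2 hepatic core genes, 9 at least 2 pancreatic core genes and 4 both. Most cells with the hepatic genes thus did not pass for the pancreatic ones. Itih2, a plasma protein gene (chromosome 2, 10094593 to 10131396), averaged 7.01 ± 4.24 in the ventral bud (21 of 27 cells) against 0.55 ± 1.87 in the dorsal bud (7 of 86 cells). Hhex (chromosome 19, 37434810 to 37440731) averaged 5.56 ± 3.96 against 0.52 ± 1.79. Afp averaged 6.73 ± 4.71 against 0.91 ± 2.23. Isl1 (chromosome 13, 116298281 to 116309689) was 0 in all 27 ventral cells against 4.62 ± 4.92 in the dorsal bud (42 of 86 cells), and Gng2, a G protein subunit gene, averaged 0.52 ± 1.69 against 4.93 ± 3.07.

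These genes differed in the same direction from each dorsal plate, as the choice of named genes required: Itih2 by 6.28 from plate 2A and 6.68 from plate 2B, Isl1 by -3.99 and -5.43. The other genes higher in the ventral bud were the plasma protein genes Ambp, Ttr, Apoa2, Fgg, Fgb and Apoe and the glucose transporter gene Slc2a2, which was 0 in all 86 dorsal cells. Those lower included the stress regulator Atf4, the p53 inhibitor Mdm2, the kinase gene Pdk3, the tRNA synthetase gene Gars, Tspan7, Qrich1, Ppp6c and Fndc3c1.

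By list, hepatic secreted proteins had a median difference of 1.92 between the ventral and the dorsal bud (10 of 14 measured members higher by at least 1, 0 lower), and liver bud transcription factors one of 0.65 (3 higher, 0 lower). Pancreatic progenitor genes went both ways, with a median of -0.18 (3 higher and 4 lower of 12). The median of all genes was -0.34, and -0.40 after median-of-ratios scaling, and relative to the former the pancreatic progenitor median was 0.16 and the hepatic secreted median 2.26. Among them Cpa1, a digestive enzyme gene of tip cells, was higher (2.48 ± 3.94 against 0.33 ± 1.52), while Rfx6, an endocrine regulator, was lower (0.75 ± 2.28 against 3.67 ± 4.17). Endocrine hormone and granule genes were lower, with a median of -1.67 (0 higher and 13 lower of 14), in step with the 20 dorsal cells of cluster 7. Gcg was 0 in the ventral bud against 2.54 ± 5.60, and endocrine progenitor genes had a median of -0.76. Biliary genes had a median of 0.96 (5 higher and 2 lower of 11), with Sox17, an endoderm regulator of the bile duct, at 3.97 ± 4.91 against 0.29 ± 1.57. Epithelial genes had a median of 0.84. Mesenchyme markers had a median of -0.92 (0 higher and 3 lower of 6), and at least 3 of them were found in 13 dorsal and 0 ventral cells. Isl1 was detected in 20 of 20 cells of cluster 7 and also in 19 of 35 cells of cluster 6, so its difference is not one of endocrine cells alone.

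In cells of cluster 1 alone, a choice made after seeing the data, 24 ventral and 27 dorsal cells could be set side by side. These cells were still unlike: 18 of the ventral ones had at least 2 hepatic core genes, 9 at least 2 pancreatic core genes and 4 both. The dorsal ones numbered 10, 24 and 9 by the same counts. The hepatic secreted median was 1.89 there, and Itih2, Hhex, Afp, Ttr, Apoa2 and Slc2a2 stayed among the 10 genes with the largest higher levels. The biliary median turned to -1.23 and the epithelial median to -0.98, the endocrine hormone median moved to -0.06, and the pancreatic progenitor median was -1.48. G2/M genes went from -0.76 in all cells to -2.75, and S phase genes from -0.24 to -1.28. Dorsal plates 2B and 2A differed from each other by -1.05 for biliary, -1.55 for epithelial, -0.65 for pancreatic progenitor genes, 1.68 for G2/M and 1.60 for S phase genes, but by 0.05 for hepatic secreted proteins. Even so, the hepatic secreted median of the ventral against the dorsal bud was 1.63 with plate 2A alone and 2.95 with plate 2B alone.

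Pancreas at E14.5 was compared with the E10.5 buds to see what differs as the organ matures. Cells of the E14.5 group carried high levels of collagen and other mesenchymal genes, and low levels of Prox1, epithelial genes and glycolysis genes. Col1a1 (chromosome 11, 94936224 to 94953042) averaged 9.25 ± 4.84 at E14.5, with 58 of 73 cells positive, against 0.73 ± 2.19 in the dorsal and 0 in the ventral bud. The lactate dehydrogenase gene Ldha (chromosome 7, 46841475 to 46855627) averaged 4.98 ± 4.61 against 12.12 ± 0.99 and 11.97 ± 0.58. Among the other genes with higher levels were the collagens Col3a1 and Col1a2, the imprinted zinc finger gene Plagl1, the pericyte and stromal marker Cd248, the growth factor gene Ptn, Itm2a, Sparcl1, Tgfbi and Islr. Among those with lower levels were the fibronectin gene Fn1, the keratins Krt8 and Krt18, the glycolytic genes Gpi1 and Pfkl, Bex1, Cadm1, Igfbp2 and Prox1.

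By list, mesenchyme markers had medians of 4.31 against the dorsal and 5.04 against the ventral bud (7 of 9 measured members higher by at least 1, 0 lower, in both). Epithelial genes had medians of -3.76 and -4.43, pancreatic progenitor genes -1.77 and -1.22, and ductal genes -2.37 and -1.15. Glycolysis genes had medians of -4.34 and -3.80, with 11 of 11 members lower in both, among them the glucose transporter gene Slc2a1 (2.14 ± 3.71 against 9.20 ± 2.49 and 7.40 ± 3.44). The cell division genes of the G2/M list had medians of -3.20 and -2.43, with 12 of 12 members lower in both, among them Birc5, a mitotic survival gene (-3.67 and -3.64). Genes of the early embryonic list had medians of -2.86 and -2.88. Hepatic secreted proteins had medians of -0.55 and -5.08. Endocrine hormone genes had medians of -1.05 against the dorsal bud (0 higher and 9 lower of 15) and 0.29 against the ventral bud (3 higher and 0 lower of 13). Acinar genes had medians of -0.27 and -0.30. Of the 18 genes on that list only 9 had deposited values, and these medians rest on 9 and 8 measured members. Spink1, a trypsin inhibitor gene, differed from the ventral bud by -2.27.

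In cells with at least 2 epithelial genes (13 at E14.5, 73 dorsal, 27 ventral) some of these directions differed. Those cells were of different kinds in each group: 12 of the 13 at E14.5 belonged to cluster 9, the endocrine progenitor-like one, and 24 of the 27 ventral cells to cluster 1. Of the dorsal cells 27 belonged to cluster 1, 20 to cluster 7, 14 to cluster 10 and 10 to cluster 6. The ductal medians were 0.23 and 0.14, the acinar medians 0.19 and 0.43, and the endocrine hormone medians 0.25 and 2.97. The pancreatic progenitor medians there were -0.22 and -0.09, and the hepatic secreted median against the ventral bud was -2.60. The endocrine progenitor median against the ventral bud was 0.72 in all cells and 5.59 in these cells, which sets cluster 9 mainly against cluster 1. Against the dorsal bud that median turned from -0.20 in all cells to 4.70 in these cells. The glycolysis medians were -4.16 and -3.59 and the G2/M medians -3.33 and -3.28 in these cells, the same direction as in all cells. The median of all genes was -0.49 against the dorsal bud and -0.61 after median-of-ratios scaling. Relative to the former, the mesenchyme median was 4.80 and the glycolysis median -3.85.

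Each E10.5 organ was compared with the E8.5 foregut to see what differs between the start of organ formation and the separate buds. The organs carried higher levels of Prox1, Igf2 and H19, and lower levels of retinoid pathway and cell division genes. The insulin-like growth factor gene Igf2 (chromosome 7, 142650766 to 142666816) averaged 8.04 ± 3.84 in the dorsal bud, 10.37 ± 0.92 in the ventral bud and 10.03 ± 2.14 in the liver, against 3.53 ± 4.42 in the foregut. Its imprinted neighbour H19, a noncoding RNA gene (chromosome 7, 142575529 to 142578143), averaged 6.81 ± 3.89, 9.99 ± 1.63 and 9.69 ± 2.66 against 2.70 ± 4.41. Crabp2 (chromosome 3, 87948666 to 87953376) averaged 1.16 ± 2.44, 2.19 ± 3.48 and 1.07 ± 2.60 against 9.02 ± 3.91. The other genes with higher levels were the retinol carrier gene Rbp4, the plasma protein genes Vtn, Ambp and Ttr, the imprinted genes Dlk1 and Rian, and the caspase gene Casp6. The other genes with lower levels were Nrcam, Rfx4 (0 in the 3 organs against 5.11 ± 3.99), the Wnt antagonist gene Sfrp1, the polarity gene Crb2, the mesenchymal regulator Zeb2, Crabp1, Bcat1, Fhl1 and Akr1b3. Rfx4 and Nrcam are leading genes of cluster 4, and Crabp1 and Crabp2 of cluster 8, and both clusters hold foregut cells alone. For these genes stage and cell type cannot be told apart.

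By list, given in the order dorsal bud, ventral bud and liver, S phase genes had medians of -3.20, -3.29 and -2.96, with 10, 10 and 9 of 10 members lower by at least 1. The replication gene Mcm5 differed by -3.62, -4.25 and -5.45. The G2/M medians were -2.73, -3.17 and -2.47, at percentiles 0, 0.05 and 8.03 among random lists matched on expression. The early embryonic list, which holds Lin28a, a regulator of developmental timing, had medians of -2.37, -2.35 and -2.67 (6 of 9 members lower in each), with Lin28a differing by -3.67, -4.11 and -6.83. Retinoid pathway genes had medians of -1.60, -2.44 and -3.45, and cholesterol synthesis genes -1.90, -1.97 and -1.94. Among random lists matched on expression the cholesterol medians lay at percentiles 0.12, 30.6 and 78.9. Those of the ventral bud and the liver were thus not low for genes of their level. Epithelial genes had medians of 3.87, 4.68 and -0.12, and pancreatic progenitor genes of 1.85, 0.94 and -0.67. Hepatic secreted proteins had medians of 0.09, 1.92 and 5.86. Cardiac markers had medians of -1.20, -1.42 and -0.50, alongside the 11 foregut cells of cluster 6 with such markers. Neural markers as a list had medians of -0.06, -0.40 and -0.64, close to the median of all genes in each contrast (-0.15, -0.54 and -0.73).

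Only 22 of the 82 foregut cells had 2 or more epithelial genes, and 59 fell in clusters 4 and 8. Of those 22 cells 11 belonged to cluster 6, most of whose foregut cells had cardiac markers, and 8 to cluster 1, so this subset is mixed. In it the early embryonic medians were -1.01, -1.38 and -0.61, the retinoid medians -1.10, -1.21 and -1.43, and the S phase medians -3.01, -2.94 and -1.68, while the G2/M median of the liver turned to 0.54. The cholesterol medians in it were -1.43, -1.05 and -0.08, so little was left of the liver's difference. The median of all genes was -0.73 between liver and foregut and -0.95 after median-of-ratios scaling, and relative to the former the S phase median of the liver was -2.22.

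**Figure D3:**
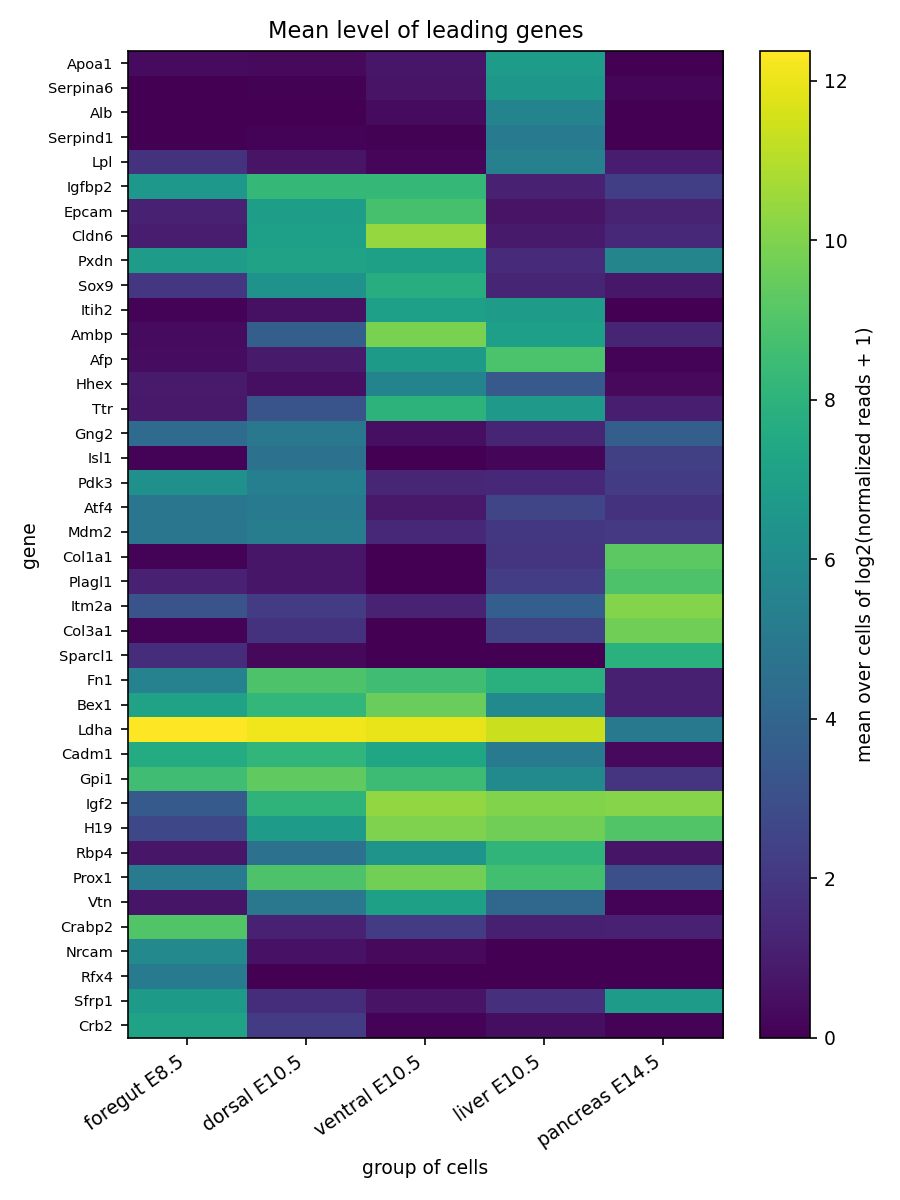
Mean over cells of log2(normalized reads + 1) in each group, as colour, for the 5 genes with the largest higher and the 5 with the largest lower levels in each of the 4 comparisons. Apoa1 stands out in the liver (6.78), Col1a1 at E14.5 (9.25) and Crabp2 in the foregut (9.02), and Ldha is lowest at E14.5 (4.98).

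Hepatic and pancreatic genes were looked for in the same cell, since the liver and the ventral pancreas share an origin in the foregut. Cells with at least 2 of 10 hepatic core genes and at least 2 of 6 pancreatic core genes were found mainly in the buds, a difference that was not tested. The dorsal bud had 10 such cells of 86 (11.6%, interval 5.72 to 20.3%) and the ventral bud 4 of 27 (14.8%, 4.19 to 33.7%). The foregut had 1 of 82 (1.22%), the E14.5 pancreas 1 of 73 (1.37%) and the liver 0 of 78, which allows a share of up to 3.85%. Most E14.5 cells were not epithelial, and among the 13 with at least 2 epithelial genes the share was 7.69%, inside the dorsal interval. The 12 foregut cells with at least 2 pancreatic core genes lay in clusters 4 (10 cells) and 8 (2 cells). The 1 foregut cell with both was in cluster 4 and had 0 epithelial genes. Foregut cells of cluster 1 gave 0 of 8 (upper bound 36.9%), too few to set against the buds. In the ventral bud 21 cells passed for hepatic genes and 9 for pancreatic genes, and independence within the group would give 7 cells with both. In the dorsal bud 12 and 35 cells passed, and independence would give 4.88. In cluster 1 alone the dorsal bud had 9 such cells of 27, where independence would give 8.89, and the ventral bud 4 of 24, where it would give 6.75. The dorsal plates had 4 of 48 cells (2A) and 6 of 38 cells (2B).

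The hepatic genes in these cells were few. Of the 10 dorsal cells, 8 carried the fibrinogen gene Fgg, 6 Fgb, 4 Afp and 0 Alb, while 9 carried Pdx1 and 9 Nkx6-2, a homeobox gene of pancreatic progenitors. Of the 4 ventral cells, 4 carried Fgg, 2 Afp and 0 Alb, while 4 carried Pdx1 and 4 Cpa1. Requiring at least 3 genes of each list left 3.49% of dorsal and 3.70% of ventral cells, and requiring 1 gave 32.6% and 40.7%.

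**Figure D4:**
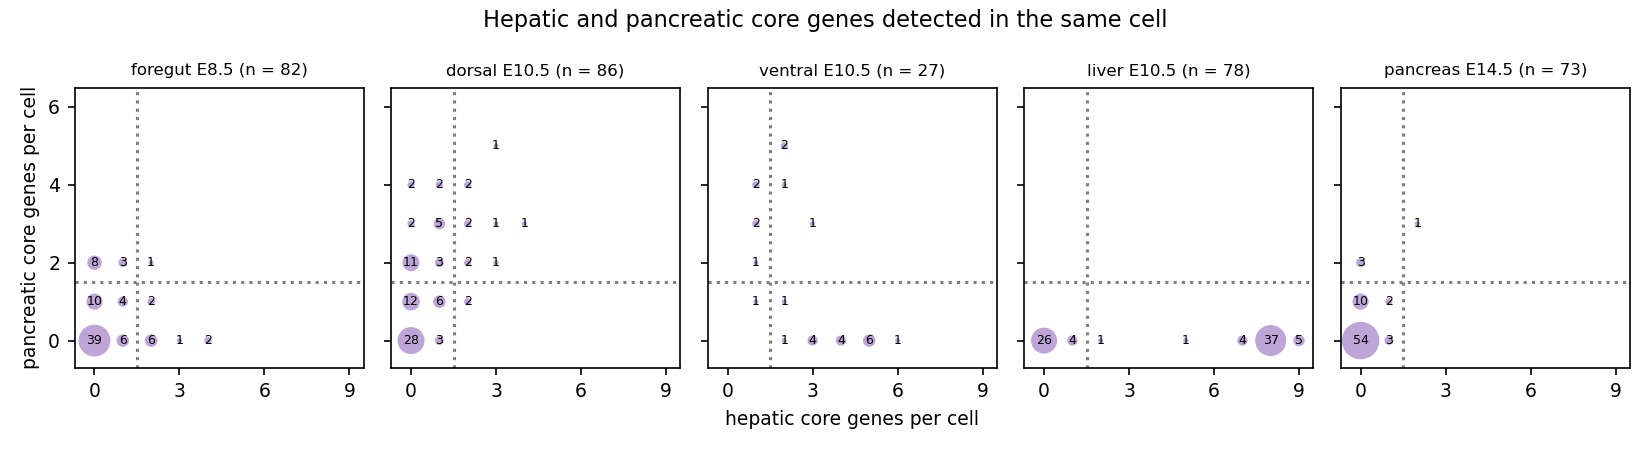
Number of hepatic core genes (x axis) and pancreatic core genes (y axis) detected in each cell, 1 panel per group, with the number of cells printed on each point, point area following it, and dotted lines at the threshold of 2 genes. The upper right field holds 10 dorsal and 4 ventral bud cells and 0 liver cells.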

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

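All tests of explanations in this part were chosen after the results were seen.

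A ribosomal RNA gene on chromosome 17 that is in no list and was not named in a comparison (39846353 to 39848827) took a mean of 4.16% of reads in the foregut, 6.21% in the dorsal bud, 2.19% in the ventral bud, 0.224% in the liver and 2.88% at E14.5. Sex-linked genes, left out of the named genes, split the dorsal plates: 48 of 48 cells of plate 2A had reads of Y-linked genes alone and 38 of 38 cells of plate 2B had reads of Xist alone, so the plates hold cells of different embryos. The liver plate held 25 cells with Y-linked reads and 26 with Xist reads. The foregut, ventral bud and E14.5 plates held 81, 21 and 58 cells with Y-linked reads and 0 with Xist reads. Sex was thus not matched between these groups and plate 2B or the liver.

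Most E14.5 cells carried collagen genes and little Prox1. Low depth is argued against, since 100% of the 12 E14.5 cells of cluster 9 had Prox1 (lower bound 73.5%) at a median of 762088 reads, against 17.2% of cluster 2 (upper bound 29.4%) at 814690 reads. Epithelial cells that took up mesenchymal RNA are also argued against, since 0 of 58 cells of cluster 2 had 2 or more epithelial genes (upper bound 6.16%). What stays open is that mesenchyme-like cells passed the gate for green fluorescence. In cluster 2 100% of the 58 cells had at least 3 mesenchyme markers, but the cluster was named from the same list, so this share is no test. The cells of cluster 2 may be ones that keep the protein after the transcript has gone, or ones sorted at background fluorescence, and the table cannot separate these.

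Foregut cells of clusters 4 and 8 carried neural-type genes such as Rfx4 and Nrcam together with Prox1. Prox1 RNA from epithelial cells of the same plate is argued against: epithelial genes reached a median of 0 of the level that their ratio to Prox1 in foregut cells of cluster 1 would give, with Krt18 at 13.4 normalized reads of 879 predicted. Sorting without regard to Prox1 stays open: 88.1% of these 59 cells had it (77.1 to 95.1%), but at means of 5.09 ± 1.99 in cluster 4 and 3.99 ± 2.09 in cluster 8 against 9.22 ± 2.12 in cluster 1, and no unsorted foregut cells are there to compare. No biological explanation was tested.

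Some bud cells carried hepatic and pancreatic core genes at once. RNA from liver cells was tested by the median ratio of hepatic core genes to a predicted level. That level came from the profile of the hepatoblast-like liver cells, scaled to the bud cells' own sum of core genes. The ratio was 0.396 in the dorsal and 0 in the ventral bud. In the dorsal bud liver RNA stays open, since several members reached the predicted level, with Fgg at 103 of 12.7 normalized reads. In the 4 ventral cells Fgg (383 of 21.9 predicted) made up most of the sum, and Trf also passed its level (9.33 of 5.98). Every other member with a predicted level above 0 fell short of it. Among them were Fgb (0 of 80.5), Apoa2 (10.4 of 86.7) and Serpina6 (0 of 25.1). The mix of hepatic genes in these 4 cells thus differed from that of the hepatoblast-like liver cells. The high Fgg raised the level predicted for the others, so the test cannot decide on liver RNA here. It stays open, as the only source of the hepatic genes or as the source of a part of them. A pair of cells in 1 well stays open in both buds, since the median gene number of these cells was 0.939 times that of other dorsal cells and 1.05 times that of other ventral cells of cluster 1, within their spread. The bud of origin, dorsal or ventral, is a biological difference that the design names and that could not be told apart from the plates.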

How the results depend on the processing

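All alternatives marked as added were chosen after seeing the data, and so was the rule for an unchanged list median, a move no larger than the gap between dorsal plates 2B and 2A for that list. Of 148 list medians under alternatives, 77 were unchanged by this rule, 64 moved and 7 reversed. Of 50 shares of cells with both programmes, 38 were unchanged and 12 moved. No paired analysis was possible because the labels name no animal. Where a value moved, the cause was not tested. Medians below are in the order named, and D, V and F stand for the dorsal bud, the ventral bud and the foregut.

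Hepatic secreted proteins stayed higher in liver than in the buds and in V than in D under every alternative. Medians of liver against D, liver against V, and V against D were 7.27, 2.34 and 2.70 with a pseudocount of 0.1, and 3.71, 2.01 and 1.40 with 10. They were 7.26, 3.41 and 3.76 as log2 ratios of linear means plus 1, and 5.12, 1.75 and 1.78 with median-of-ratios scaling. Without cells of other types they were 8.17, 5.86 and 1.52, in cells with Prox1 6.49, 3.39 and 1.86, and with no filter on low values 5.41, 2.01 and 1.70. In cells with epithelial genes (added) they were 8.84, 6.83 and 1.55. The medians of liver against D and V were 5.89 and 2.53 in cells with at least 2000 genes, and 5.06 and 1.73 with scaling by total reads (added). V against D gave 1.63 with plate 2A alone, 2.95 with plate 2B alone and 2.10 without cluster 10 (added).

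Pancreatic progenitor genes stayed lower in liver. Against D and V the medians were -3.76 and -2.02 with a pseudocount of 0.1, and -3.21 and -3.83 as ratios of linear means. Against D they were -1.29 with a pseudocount of 10 and -3.20 without cells of other types. V against D gave -1.48 in cluster 1 alone (added).

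Early embryonic genes stayed lower in D, V and liver than in F. Their medians were -3.50, -3.79 and -4.26 with a pseudocount of 0.1, -1.23, -1.28 and -1.30 with 10, and -1.01, -1.38 and -0.61 in cells with epithelial genes (added). Of the 22 foregut cells kept there, 11 belonged to cluster 6, so this is no comparison of epithelial cells. As ratios of linear means they were -1.30 for D and -1.44 for liver.

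At E14.5 the acinar and endocrine hormone medians depended on which cells were kept. Acinar medians against D and V were -0.48 and -0.48 with a pseudocount of 0.1, and -0.0945 and -0.14 with 10. They reversed to 0.18 and 0.34 without cells of other types, and to 0.19 and 0.43 in cells with epithelial genes (added). As ratios of linear means they were -0.64 and 0.67, the latter reversed. Against V they were -0.0067 in cells with Prox1 and -0.0261 with no filter on low values. Endocrine hormone medians against D were -1.44 and -0.61 with pseudocounts of 0.1 and 10, -1.32 as ratios of linear means and -0.14 in cells with Prox1. They reversed to 0.60 without cells of other types and to 0.25 in cells with epithelial genes (added). Against V they were 3.95 as ratios of linear means, 3.25 without cells of other types, 1.22 in cells with Prox1 and 2.97 in cells with epithelial genes (added).

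The share of cells with both programmes was 0% in F with detection at 20 normalized reads (which allows up to 3.66%) and 0% among the 22 foregut cells with epithelial genes (added). With at least 3 genes of each list it was 0% in F (up to 3.66%), 3.49% in D, 3.70% in V and 0% at E14.5 (up to 4.11%). With at least 1 gene it was 12.2% in F, 32.6% in D and 40.7% in V. At E14.5 it was 9.09% without cells of other types and 7.69% in cells with epithelial genes (added), and D had 33.3% in cluster 1 alone (added).

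Over all lists and contrasts, 83 medians of 1 or more in size were compared: 0 reversed with median-of-ratios scaling, 0 with scaling by total reads, 7 in cells with epithelial genes and 7 without cells of other types. These 7 include the epithelial and mesenchyme or cardiac lists, some of which define the cells kept, so the counts do not rank the choices. Lists that define no subset reversed too. In cells with epithelial genes these were the ductal list at E14.5 against D and V (from -2.37 and -1.15 to 0.23 and 0.14), the endocrine hormone list against D (-1.05 to 0.25) and the G2/M list of liver against F (-2.47 to 0.54). The number of clusters went from 7 to 15 under the alternatives. Liver cells had the most reads and E14.5 cells the fewest, and after thinning to 500000 reads the same number of cells held both programmes.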

Other observations

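Some gene lists outside the lead of each comparison also differed between groups, and the tests of cell subsets here were chosen after the results were seen. Notch pathway genes differed between the buds mainly through the receptor genes Notch1 (5.33 ± 4.00 in the ventral against 2.68 ± 3.83 in the dorsal bud) and Notch2 (6.47 ± 2.04 against 4.02 ± 2.93). The list's median was 0.28 with 2 members higher and 0 lower of 7, but it turned to -0.52 in cells of cluster 1 alone. In the liver Notch2 was higher than in the dorsal bud (7.18 ± 2.22) while Notch1 was lower (0.83 ± 2.42). Wnt response genes had a median of -0.72 in the ventral against the dorsal bud, and of -0.18 in cells of cluster 1 alone, with Axin2, a direct target of the pathway, at 0.33 ± 1.43 against 1.69 ± 2.68. In the liver Znrf3, a Wnt receptor regulator, averaged 7.38 ± 4.23 against 3.67 ± 3.12 in the dorsal and 3.72 ± 4.09 in the ventral bud, and Lgr5, a receptor for R-spondins, 3.16 ± 4.49 against 1.71 ± 3.46 and 0.58 ± 2.10. The Wnt list as a whole had liver medians of -0.17 against the dorsal bud (2 higher and 2 lower of 8) and 0.20 against the ventral bud (2 higher and 0 lower of 8).

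At E14.5 the BMP target genes Id1, Id2 and Id3 were lower than in both buds: Id2 averaged 1.81 ± 3.31 against 6.82 ± 3.49 in the dorsal and 8.80 ± 2.94 in the ventral bud. The BMP list's medians against the dorsal and ventral buds were -1.02 and -0.30 in all cells, and -3.18 and -5.41 in cells with epithelial genes, which at E14.5 are mostly those of cluster 9. Cholesterol synthesis genes had medians of -1.88 and -1.44 against the dorsal and ventral buds, among them Sqle, which oxidizes squalene (-2.26 and -2.23). Rdh10, which makes retinaldehyde, was higher (3.49 ± 4.40 against 0.19 ± 1.02 and 0), as was Jag1, a Notch ligand gene (3.38 ± 3.61 against 0.75 ± 1.86 and 0.76 ± 2.05). Their lists were not higher as a whole, with medians of -0.03 and -0.29 for retinoid and 0.24 and -0.71 for Notch genes. In cells with epithelial genes the retinoid medians were -1.23 and -1.68, and the Notch median against the dorsal bud turned to -1.47, and to -0.10 in all cells with median-of-ratios scaling. Genes of dissociation stress had medians of 0.04 against the dorsal and 0.61 against the ventral bud, with Jun, an immediate early gene, at 5.43 ± 4.30 against 4.66 ± 3.75 and 3.30 ± 3.95. Barx1, a stomach mesenchyme regulator, averaged 2.03 ± 3.59 in the dorsal and 0 in the ventral bud, and Nkx2-3, a gut mesenchyme gene, 2.11 ± 3.60 at E14.5.

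Between the dorsal plates, G2/M genes were higher on plate 2B by a median of 1.68 (12 of 12 members by at least 1) and S phase genes by 1.60, while glycolysis genes differed by -1.28. The plates also held different cells: cluster 6 made up 44.7% of plate 2B and 12.5% of plate 2A, cluster 10 made up 29.2% of plate 2A and 0 of the 38 cells of plate 2B (which allows up to 7.89%), and cells with markers of other types were 34.2% of plate 2B and 10.4% of plate 2A. The plates hold cells of different sex as well, so cell type, sex, embryo and plate cannot be told apart for these lists.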
